A study of Homo sapiens with 9 samples.

How the data were processed

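Total RNA from 9 samples of cells labelled Hep3B was measured on Illumina expression BeadChips, 1 array per sample: 3 of a control line with an shRNA against luciferase, 3 of the line AMPK shRNA 1 and 3 of the line AMPK shRNA 2. Groups and replicate numbers came from the sample titles. Per the labels' protocols, cells grew in DMEM with 10% fetal bovine serum, RNA was extracted with Trizol and an RNeasy column, and biotinylated cRNA was made with a MessageAmp kit.

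The deposited scanner table holds, per the file headers, an average intensity, a detection p-value, a bead number and a bead standard error for each sample on a linear scale, not background-subtracted. It has 34694 entries, 34602 human and 92 ERCC controls, of which at most 2 on an array had a detection p under 0.05. The intensities are per gene, not per probe: 7007 human entries have a detection p that is not a whole multiple of the step given by 770 negative controls (to within 0.006 of a step) on all 9 arrays, as an average over probes would, so a gene bright on one probe can have a high detection p. The series' value table, deposited by the authors, has 34687 entries (7 fewer) and equals the intensity times 1 constant per array, between 0.9557 and 1.074; it is linear and not centred, its column medians were 109.4 to 117.2, and how the constants were chosen is not stated. No upstream software version is stated. Gene symbols are those of the table and can be old. Of 31332 entries with an Entrez ID, 24091 matched the RefSeq gene table of GRCh38.p14, which was used for current names only; cytobands are those of the deposited table, and the build is not stated. For 3270 entries with only a UniGene ID there is no symbol.

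Background was corrected by normexp with the negative-control distribution inferred from the detection p-values, with an offset of 16, and the arrays were quantile-normalized on the log2 scale (neqc of limma 3.58.1 in R 4.3.3). A fold change is on this scale and understates the change of dim genes. Genes with a detection p under 0.05 on at least 3 of the 9 arrays were tested, 15560 entries, of which 14172 have a symbol. One linear model with 3 group means was fitted to all 9 arrays (lmFit, contrasts.fit, eBayes), so that the groups share one estimate of the spread (6 residual and 3.47 prior degrees of freedom), with no covariate. AMPK shRNA 1 against control, AMPK shRNA 2 against control, the mean of both lines against control, and AMPK shRNA 2 against AMPK shRNA 1 were tested, p-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. A named gene detected in one group and on no array of the other got a lower bound for its fold in place of the fitted value.

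The 38 gene lists, the tests, the alternatives and the rule for naming genes were fixed before the files were opened, except a filter on signal that was added later. Lists with at least 5 genes tested (36) went through camera with a preset correlation of 0.01 and again with the correlation estimated per list. A further list was written after some levels had been seen. The design had assumed several probes per gene, of which the brightest would be kept; with values per gene that choice did not arise. Named were the measured AMPK subunits, in each comparison the 6 largest called increases and decreases whose arrays do not overlap, the 10 higher and 10 lower called in both lines with the largest smaller change, the 4 largest called in opposite directions, and from each list up to 4 members called in both lines or else up to 2 called in one. Entries with no symbol or a placeholder were passed over, as was the dimmer of 2 entries with the same current symbol. A list member that the table places on chromosome Y was left out of the naming. Not every gene and list that was tested is printed.

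Alternatives were other background corrections, median scaling, cyclic loess, the authors' value table, no filter and a stricter one (detection p under 0.01 on all 9 arrays), a fit of only the groups compared, the replicate number as a block, a variance prior with trend and robust estimation, array weights, a test against a fold of 1.2, and leaving out each array in turn. For the overlap of the lines, unchanged groups were simulated against the real controls 100 times. The steps were tested on simulated data with known changes for AMPK shRNA 1 against control over 15560 entries: 35.8% of 67 genes changed 1.5-fold were recovered, 71.6% of 67 changed 2-fold and 87.9% of 66 changed 4-fold, with 9 unchanged genes called, 0 calls in the unchanged line and 0 of 100 random lists called. The simulated genes varied independently, so the 0 of 100 does not show how often camera calls unchanged lists of genes that vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.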

Results

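Gene expression was measured on 9 Illumina BeadChip arrays in cells labelled Hep3B, a human hepatocellular carcinoma line. The arrays fell into 3 groups of 3: a control line with an shRNA against luciferase, and the lines AMPK shRNA 1 and AMPK shRNA 2, in which AMP-activated protein kinase (AMPK) was targeted. The labels name neither the subunit targeted nor whether the 3 RNA samples of a line came from separate cultures, so the p-values below measure the spread between these samples, part of which can be technical. Of 34602 human genes and transcripts on the array, 13715 to 14425 per array (39.6 to 41.7%) had a detection p under 0.05. The median intensity was 106.4 to 116.4 per array, against a mean of 98.3 to 107 for the negative controls as inferred from the detection p-values. Arrays of one group correlated with a mean Pearson r of 0.9868 to 0.9937 per array across genes, which are not independent replicates. After a filter on detection, 15560 genes and transcripts were tested with limma. The number of arrays limits the precision of every comparison.

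The AMPK subunits came first, because they check the labels. PRKAA1 (5p13.1b), which encodes the catalytic subunit alpha 1, had a normalized log2 intensity of 7.86 ± 0.09 (SD, n = 3) in the control, 6.46 ± 0.14 in AMPK shRNA 1 and 6.26 ± 0.15 in AMPK shRNA 2. Its log2 fold change was -1.40 (SE 0.11, limma with Benjamini-Hochberg adjustment, adjusted p = 0.000699) in AMPK shRNA 1 and -1.60 (SE 0.11, adjusted p = 0.000665) in AMPK shRNA 2, which left 37.9% and 33% of the control signal. All 6 arrays of the lines lay below all 3 control arrays. The measured intensity of PRKAA1 fell from 340 ± 25.3 to 166 ± 6.83 and 165 ± 16. The other catalytic subunit gene, PRKAA2, and PRKAG3 were not above background on any array. PRKAB1, PRKAB2, PRKAG1 and PRKAG2 were not called in either line. Of these, PRKAB2 had the largest log2 fold change, 0.21 in AMPK shRNA 1 and 0.35 in AMPK shRNA 2, with adjusted p = 0.35 and 0.156 by limma with Benjamini-Hochberg adjustment.

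**Figure D1:**
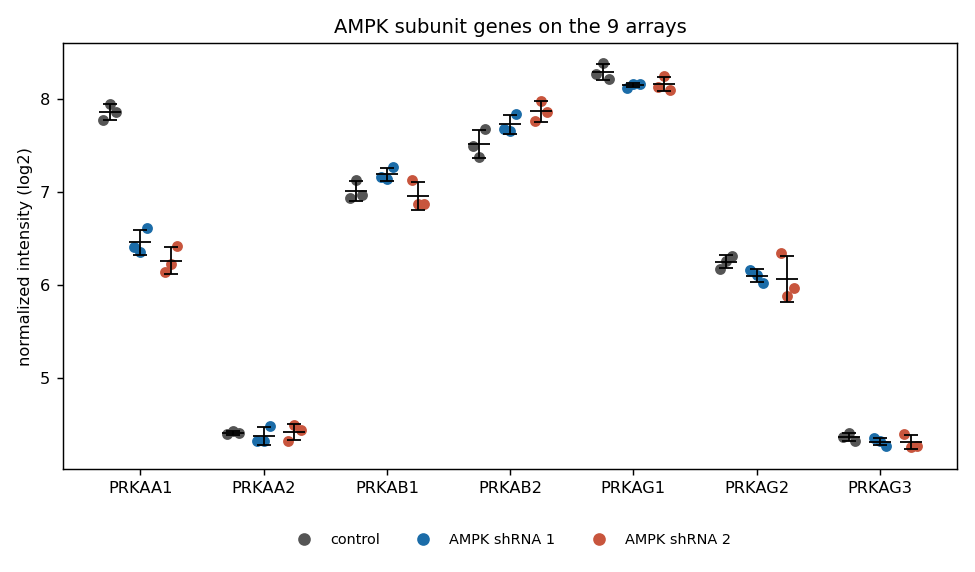
Normalized log2 intensity of the 7 AMPK subunit genes on each of the 9 arrays (points), with the mean and SD of each group (black bars). PRKAA1 was lower on all 6 arrays of the AMPK shRNA lines, at means of 6.46 and 6.26 against 7.86 in the control.

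AMPK shRNA 1 was compared with the control to ask which transcripts changed in a line with lowered PRKAA1 transcript. AMPK protein and activity were not measured. The largest increases were in NUPR1 (log2 fold change 2.39, SE 0.31, limma with Benjamini-Hochberg adjusted p = 0.0104), HBB (1.90, SE 0.40, adjusted p = 0.0423), ALDH3A1 (1.82, SE 0.27, adjusted p = 0.0137), AGR2 (1.74, SE 0.24, adjusted p = 0.0122), CLCA2 (1.68, SE 0.34, adjusted p = 0.0368) and INHBE (1.48, SE 0.21, adjusted p = 0.0137). NUPR1 went from a log2 intensity of 6.06 ± 0.27 to 8.45 ± 0.25 (SD, n = 3). The largest decreases were in HDHD1A, now PUDP (-1.59, SE 0.10, limma with Benjamini-Hochberg adjusted p = 0.000605), PRKAA1 itself, STS-1, now UBASH3B (-1.38, SE 0.14, adjusted p = 0.00388), NT5E (-1.32, SE 0.25, adjusted p = 0.0311), IL1A (-1.25, SE 0.22, adjusted p = 0.0233) and GLTP (-1.20, SE 0.08, adjusted p = 0.000605). In total 232 genes were higher and 189 lower, and 49 of them changed at least 2-fold. With the arrays scaled to one median instead of quantile-normalized, 125 were higher and 470 lower, and the median log2 fold change of all genes tested was -0.13. The authors' value table gave 210 higher and 1567 lower. The counts fell without any 1 array of the control or of the line, which fewer samples alone can cause. They were 29 higher and 19 lower without control replicate 1, 40 and 18 without control replicate 2, and 19 and 9 without control replicate 3. Leaving out an array of the line itself gave 90 and 56 (replicate 1), 33 and 21 (replicate 2), and 56 and 41 (replicate 3). Without AMPK shRNA 2 replicate 1, which enters through the shared estimate of the spread, they were 488 and 403. Of the 54 genes named here and below that were called in this line, 13 to 21 kept the call without one control array and 21 to 32 without one array of the line, and none changed sign.

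Among 38 lists of genes fixed before the data were examined, 36 had enough members to test with camera, and 13 shifted in AMPK shRNA 1, 8 up and 5 down. None of the 13 kept an adjusted p under 0.05 with an estimated correlation between genes in place of the preset one. The amino acid stress response, the targets of ATF4, had 28 members tested, of which 6 were higher, 0 lower and 22 not called, and 18 were higher when adjusted over the list alone. The median log2 fold change was 0.40 (camera with Benjamini-Hochberg adjusted p = 2.33e-12; adjusted p = 0.264 with an estimated correlation). ASNS rose by 1.02 (SE 0.19, limma with Benjamini-Hochberg adjusted p = 0.0272), CTH by 0.75 (adjusted p = 0.0107) and TRIB3 by 0.58 (adjusted p = 0.0138), beside NUPR1. The call of ASNS was lost without any one array of the control or of its own line, where its adjusted p reached up to 0.102. The NRF2 and antioxidant list had 3 of 26 members higher, 0 lower and 23 not called, 9 higher when adjusted over the list alone, and a median of 0.12 (camera adjusted p = 6.49e-05; adjusted p = 0.0867 with an estimated correlation). GPX2 rose by 0.91 (SE 0.09, limma with Benjamini-Hochberg adjusted p = 0.00223) and FTH1 by 0.77 (SE 0.09, adjusted p = 0.00531).

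Lipid and mitochondrial lists were tested in the same way. Of 18 fatty acid synthesis genes, 1 was higher, ACSS2 (0.57, limma with Benjamini-Hochberg adjusted p = 0.0204), 17 were not called, and 3 were higher when adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.0086; adjusted p = 0.208 with an estimated correlation); the median was 0.00 with median scaling (camera adjusted p = 0.118). Of 23 cholesterol synthesis genes, 1 was higher, TM7SF2 (0.89, limma with Benjamini-Hochberg adjusted p = 0.0137), and 22 were not called, with 3 higher when adjusted over the list alone. The median was 0.19 (camera adjusted p = 0.00103; adjusted p = 0.427 with an estimated correlation), but -0.01 with median scaling and with the authors' value table. Fatty acid oxidation had 0 of 19 genes called and a median of 0.11 (camera adjusted p = 0.03; adjusted p = 0.427 with an estimated correlation), which turned to -0.05 with median scaling and -0.03 with the value table. That call was lost without control replicate 1 (camera adjusted p = 0.0639), without AMPK shRNA 1 replicate 2 (adjusted p = 0.0674) and without AMPK shRNA 1 replicate 3 (adjusted p = 0.143). The mitochondrial biogenesis list had 1 of 15 genes lower, DNM1L (-0.59, limma with Benjamini-Hochberg adjusted p = 0.0137), 14 not called, 3 lower when adjusted over the list alone, and a median of -0.11 (camera adjusted p = 0.0086; adjusted p = 0.427 with an estimated correlation). Among kinases upstream of or related to AMPK, 1 of 17 was called, STRADB (-0.43, limma with Benjamini-Hochberg adjusted p = 0.0368). Of 56 oxidative phosphorylation genes 1 was lower, COX8A (-0.89, SE 0.08, adjusted p = 0.000967).

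Further lists covered cell growth and stress. Of 45 mitosis and G2/M genes, 0 were higher, 2 lower and 43 not called, with 7 lower and 1 higher when adjusted over the list alone, and the median was -0.17 (camera with Benjamini-Hochberg adjusted p = 5.27e-05; adjusted p = 0.107 with an estimated correlation). CENPA fell by 0.53 on the log2 scale (SE 0.08, limma adjusted p = 0.0151). Of 30 MYC targets and ribosome biogenesis genes, 0 were higher, 2 lower and 28 not called, with 6 lower when adjusted over the list alone, and the median was -0.29 (camera adjusted p = 4.29e-07; adjusted p = 0.427 with an estimated correlation). These were POLR1A (-0.60, limma adjusted p = 0.0164) and FBL (-0.39, adjusted p = 0.0424). Of 41 genes of DNA replication and G1/S, 1 was called, MCM6 (0.35, limma adjusted p = 0.0476), and the list did not shift (camera adjusted p = 0.481). The YAP and TEAD targets had 3 of 19 genes lower, 1 higher and 15 not called, among them AXL (-0.71), ASAP1 (-0.48) and JUB, now AJUBA (0.55), with a median of -0.22 (camera adjusted p = 0.0048; adjusted p = 0.427 with an estimated correlation). Heat shock genes had a median of -0.17 with 0 of 21 called (camera adjusted p = 0.00831; adjusted p = 0.427 with an estimated correlation). The histone list had 2 of 15 genes higher, 13 not called, 5 higher and 1 lower when adjusted over the list alone, and a median of 0.32 (camera adjusted p = 0.00252; adjusted p = 0.264 with an estimated correlation). The interferon list had 0 of 39 genes called and a median of 0.12 (camera adjusted p = 0.00334; adjusted p = 0.525 with an estimated correlation).

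**Figure D2:**
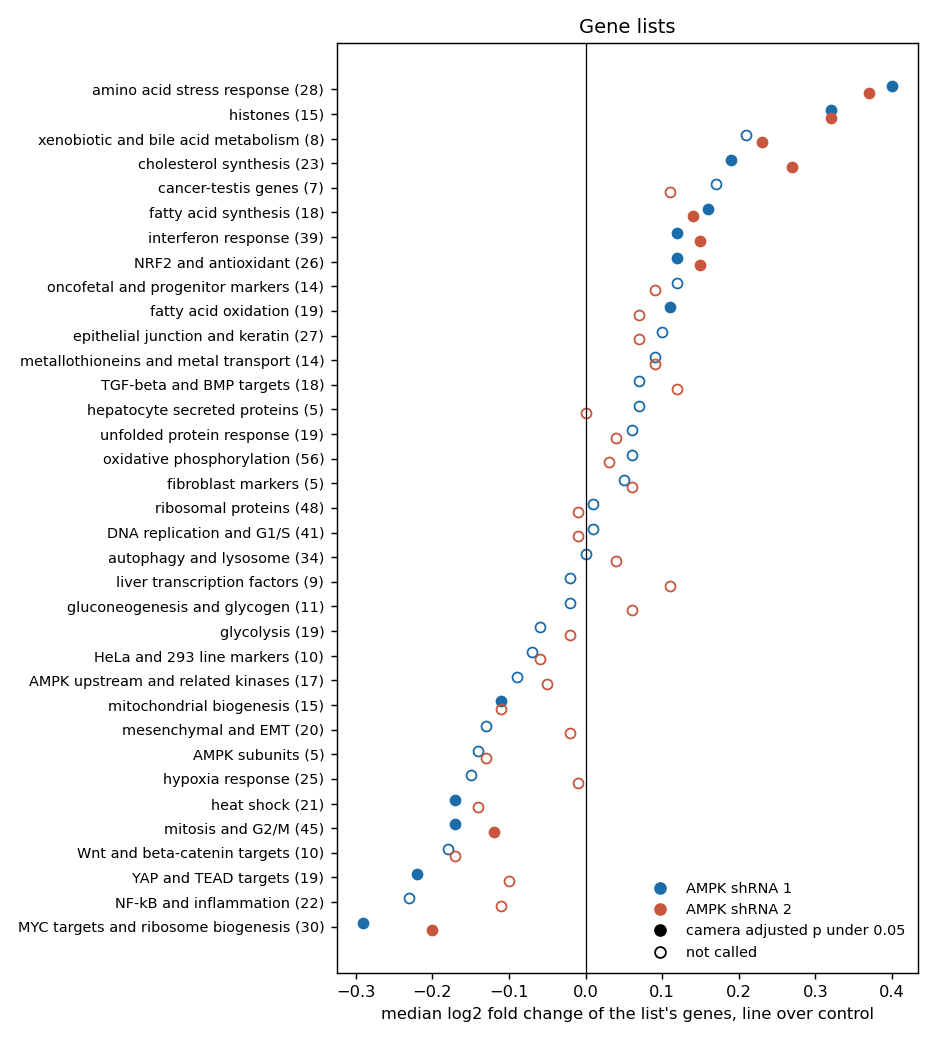
Median log2 fold change over control of the genes of each of 35 lists (number tested in brackets) in AMPK shRNA 1 and AMPK shRNA 2, filled where camera with the preset correlation gave an adjusted p under 0.05. The amino acid stress response lay highest, at 0.40 and 0.37; the median of cholesterol synthesis and fatty acid oxidation in AMPK shRNA 1 changed sign with median scaling.

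AMPK shRNA 2 was compared with the same controls, as a second shRNA line. NUPR1 again rose most (log2 fold change 1.99, SE 0.31, limma with Benjamini-Hochberg adjusted p = 0.0285), to 8.05 ± 0.72 (SD, n = 3). AGR2 (1.38, SE 0.24, adjusted p = 0.0383), INHBE (1.30, SE 0.21, adjusted p = 0.0336) and CNTNAP2 (1.15, SE 0.10, adjusted p = 0.00158) followed. MMP10 and RAB7B were not well above background on any control array, so only a bound holds for them: the mean of the line over the mean of, per array, the dimmest signal detected or the gene's own. MMP10 was at least 2.29-fold higher (limma adjusted p = 0.000665) and RAB7B at least 1.67-fold (adjusted p = 0.0497). The largest decreases were in PRKAA1, HDHD1A (-1.44, SE 0.10, limma with Benjamini-Hochberg adjusted p = 0.000665), GLTP (-1.17, SE 0.08, adjusted p = 0.000665), COX8A (-0.94, SE 0.08, adjusted p = 0.00105), ETV6 (-0.92, SE 0.11, adjusted p = 0.00889) and NKD2 (-0.88, SE 0.17, adjusted p = 0.0497). In total 93 genes were higher and 83 lower, 15 of them at least 2-fold. Median scaling gave 49 higher and 63 lower, and the values the authors deposited gave 105 and 668. The counts were 7 higher and 5 lower without control replicate 1, 18 and 10 without control replicate 2, and 10 and 8 without control replicate 3. They were 367 and 234 without AMPK shRNA 2 replicate 1, 15 and 11 without replicate 2, and 13 and 9 without replicate 3 of that line. Leaving out an array of AMPK shRNA 1 gave 46 and 39 (replicate 1), 30 and 18 (replicate 2), and 49 and 38 (replicate 3). Of 37 named genes called in this line, 9 to 15 kept the call without one control array, all 37 without AMPK shRNA 2 replicate 1, and 15 without either other array of the line.

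In AMPK shRNA 2, 10 lists shifted by camera, 8 up and 2 down, and 1 of them, NRF2 and antioxidant, passed with an estimated correlation. That list had 2 of 26 genes higher, 0 lower and 24 not called, 7 higher when adjusted over the list alone, and a median of 0.15 (camera with Benjamini-Hochberg adjusted p = 4.81e-06; adjusted p = 0.0458 with an estimated correlation). GPX2 rose by 0.74 and FTH1 by 0.85 (limma adjusted p = 0.00889 and 0.00408). GPX2 lost its call without control replicate 1, control replicate 3 or AMPK shRNA 2 replicate 3, where its adjusted p reached up to 0.0616. In the amino acid stress response 5 of 28 genes were higher, 0 lower and 23 not called, with 18 higher and 1 lower when adjusted over the list alone and a median of 0.37 (camera adjusted p = 6.86e-11; adjusted p = 0.329 with an estimated correlation). ASNS rose by 1.03, CTH by 0.61 and TRIB3 by 0.52 (limma adjusted p = 0.0437, 0.0328 and 0.0344). When 1 array was left out, ASNS kept its call in this line only without AMPK shRNA 2 replicate 1, and its adjusted p otherwise reached up to 0.143. Cholesterol synthesis had a median of 0.27, with 1 of 23 genes higher, TM7SF2 (0.95), and 4 higher when adjusted over the list alone (camera adjusted p = 4.81e-06; adjusted p = 0.406 with an estimated correlation). Fatty acid synthesis had 0 of 18 called, 2 higher when adjusted over the list alone, and a median of 0.14 (camera adjusted p = 0.0254; adjusted p = 0.23 with an estimated correlation). Mitosis and G2/M had a median of -0.12 with 1 of 45 lower and 3 lower when adjusted over the list alone (camera adjusted p = 4.72e-05; adjusted p = 0.117 with an estimated correlation), and CENPA fell by 0.43. MYC targets had a median of -0.20, with 0 of 30 called and 5 lower when adjusted over the list alone (camera adjusted p = 1.78e-05; adjusted p = 0.583 with an estimated correlation). Histones had 1 of 15 higher and a median of 0.32 (camera adjusted p = 0.0132; adjusted p = 0.348 with an estimated correlation), HIST1H2BD, now H2BC5, at 0.58. The interferon list had 0 of 39 called and a median of 0.15 (camera adjusted p = 0.00438; adjusted p = 0.587 with an estimated correlation). The xenobiotic and bile acid list had 0 of 8 called and a median of 0.23 (camera adjusted p = 0.0132; adjusted p = 0.23 with an estimated correlation).

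Of the 9 shifts given here, 4 lost their call when 1 array was left out, by camera with Benjamini-Hochberg adjustment. Fatty acid synthesis did so without control replicate 2 (median 0.15, adjusted p = 0.0668), AMPK shRNA 2 replicate 2 (0.11, adjusted p = 0.0901) and AMPK shRNA 2 replicate 3 (0.08, adjusted p = 0.0697), and also with median scaling (0.08, adjusted p = 0.117). The xenobiotic list did so without control replicate 2, where its median stayed at 0.23 (adjusted p = 0.0544), and histones without AMPK shRNA 2 replicate 1 (0.11, adjusted p = 0.154). The interferon list did so without AMPK shRNA 2 replicate 2 (0.08, adjusted p = 0.171) or 3 (0.07, adjusted p = 0.198).

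The size of these medians depended on the processing and on single arrays. Over 22 alternative settings, the lowest and highest median in AMPK shRNA 1 were 0.17 and 0.43 for the amino acid stress response, 0.02 and 0.17 for NRF2 and antioxidant, 0.01 and 0.16 for interferon, 0.09 and 0.38 for histones, 0.00 and 0.18 for fatty acid synthesis, -0.01 and 0.26 for cholesterol synthesis and -0.05 and 0.13 for fatty acid oxidation. They were -0.44 and -0.23 for MYC targets, -0.33 and -0.14 for mitosis and G2/M, -0.36 and -0.09 for YAP and TEAD targets, -0.29 and -0.08 for mitochondrial biogenesis and -0.26 and -0.13 for heat shock. In AMPK shRNA 2 they were 0.21 and 0.43 for the amino acid stress response, 0.04 and 0.19 for NRF2 and antioxidant, 0.02 and 0.26 for interferon, 0.06 and 0.37 for histones, 0.02 and 0.16 for fatty acid synthesis, 0.12 and 0.39 for cholesterol synthesis, 0.05 and 0.31 for the xenobiotic list, -0.33 and -0.12 for MYC targets and -0.21 and -0.11 for mitosis and G2/M.

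Both lines together were compared with the control for changes common to the 6 arrays. In this comparison 363 genes were higher and 343 lower, 35 at least 2-fold. With median scaling 151 were higher and 460 lower, and with the authors' values 231 were higher and 1882 lower. The counts were 59 higher and 43 lower, 63 and 32, and 65 and 41 without control replicates 1, 2 and 3. They were 220 and 204, 178 and 164, and 223 and 214 without AMPK shRNA 1 replicates 1, 2 and 3, and 747 and 624, 232 and 219, and 172 and 176 without AMPK shRNA 2 replicates 1, 2 and 3. Of the lists, 14 shifted by camera, 9 up and 5 down, and 0 with an estimated correlation. The amino acid stress response had 12 of 28 genes higher and 16 not called, with a median of 0.39 (camera with Benjamini-Hochberg adjusted p = 2.52e-12; adjusted p = 0.232 with an estimated correlation).

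Genes called in each line by itself were also set against each other. In the same direction in both lines, 78 genes were higher and 70 lower, and 0 were called in opposite directions; 16 and 12 of these have no symbol or a placeholder. The higher ones with the largest change in the weaker line were NUPR1, AGR2, MMP10, INHBE, RAB7B, CNTNAP2, ASNS, BTF3L4 and ZNF323, now ZSCAN31. BTF3L4 rose by 1.00 and 0.98, and ZNF323 by 1.14 and 0.98. The lower ones were HDHD1A, PRKAA1, GLTP, COX8A, NKD2, TMED10, STS-1, TMED10P, BMPR2 and SIX4. TMED10 changed by -0.94 and -0.87, and its pseudogene TMED10P by -0.92 and -0.84; cross-hybridization between them was not tested. BMPR2 changed by -0.76 and -0.83, and SIX4 by -0.74 and -0.84. Of 36 named genes called in both lines, 9 kept both calls in every one of 21 settings that tested them: PRKAA1, HDHD1A, GLTP, MMP10 (not tested with the stricter filter), CNTNAP2, COX8A, ZNF323, TMED10P and FTH1. In the test against a fold of 1.2, 7 of the 9 kept both calls, all but TMED10P and FTH1. Because both comparisons used the same 3 control arrays, unchanged groups were simulated against those controls 100 times. The simulations gave 0 genes called in both lines in either direction, and independent lists of these sizes would share 1.4 higher and 1 lower. The log2 fold changes of the 15560 genes correlated at 0.78 between the lines against 0.5 in the simulations, across genes, which are not independent replicates. Their covariance was 0.045 against 0.0112 simulated (highest 0.0119), a difference of 0.0338. The sign was shared by 78.1% of genes, against 66.7% simulated. The controls cannot be split with at least 2 arrays on each side, so part of the excess may come from the shared controls. The counts called in both lines were 7 higher and 5 lower, 18 and 8, and 8 and 6 without control replicates 1, 2 and 3, and 33 and 23, 18 and 10, and 29 and 18 without AMPK shRNA 1 replicates 1, 2 and 3. Without AMPK shRNA 2 replicates 1, 2 and 3 they were 273 and 152, 15 and 10, and 13 and 9.

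**Figure D3:**
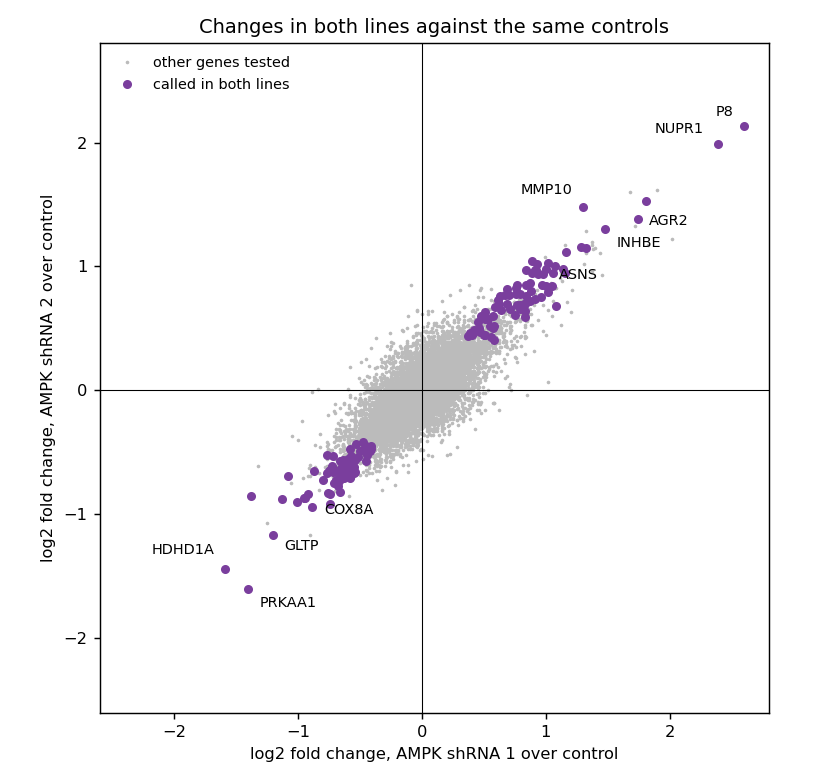
Log2 fold change over the same 3 controls in AMPK shRNA 1 (x axis) and AMPK shRNA 2 (y axis) for the genes tested, with genes called in both lines in purple. All 148 called in both lie in the quadrants of equal direction; P8 is a second entry for NUPR1.

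AMPK shRNA 2 was compared with AMPK shRNA 1 to ask whether the lines differed. By limma with Benjamini-Hochberg adjustment 0 genes were higher and 0 lower, with a smallest adjusted p of 0.0744; 687 genes had an unadjusted p under 0.05, where 778 would by chance. The count was 0 in every alternative run, including each of the 9 fits without 1 array. PRKAA1 differed by -0.20 (SE 0.11, limma adjusted p = 0.999). Of 36 lists, 0 shifted by camera, with a smallest adjusted p of 0.136, but 14 were called in at least 1 of 22 alternative settings, up to 8 in 1 setting. Of the 421 genes called in AMPK shRNA 1, 419 changed in the same direction in AMPK shRNA 2, and 403 did so at an unadjusted p under 0.05. Of the 176 called in AMPK shRNA 2, 176 and 173 did so in AMPK shRNA 1. These shares also rest on the shared controls.

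AMPK shRNA 2 replicate 1 stood apart from the other samples of its line. It correlated at 0.9854 and 0.9881 with them, against 0.9923 between those, and its array weight was 0.341 against 0.74 to 1.82 for the other 8 arrays. The median log2 difference of the hypoxia list between it and the mean of the other samples of the line was -0.48, with 24 of 25 genes below. The amino acid stress response lay at -0.27 and the interferon list at -0.43, while cholesterol synthesis and MYC targets lay at 0.47 and 0.46. The basal and squamous list lay at -0.29, with 33 of 35 genes below. Against the mean of the controls, the median of the hypoxia list was -0.34 in this sample, and 0.36 and 0.12 in replicates 2 and 3 of its line. It was also unequal within AMPK shRNA 1, at -0.30, -0.22 and 0.10 in replicates 1, 2 and 3. NUPR1 was at 7.25 in it against 8.45 in the mean of the others, and HBB at 6.28 against 7.97. PRKAA1 (6.14 against 6.32), GLTP (9.56 against 9.65) and COX8A (12.22 against 12.23) were close to the other arrays of the line.

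**Figure D4:**
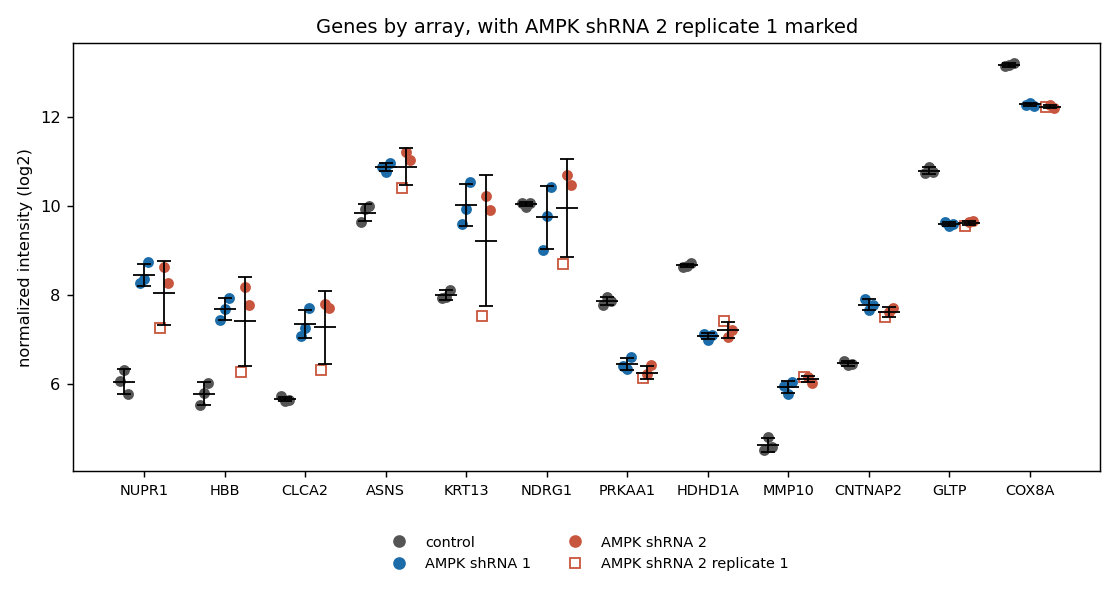
Normalized log2 intensity of 12 genes on each of the 9 arrays (points), with the mean and SD of each group (black bars) and AMPK shRNA 2 replicate 1 as an open square. In that sample NUPR1 was at 7.25 against 8.45 in the mean of the others of its line, while COX8A was at 12.22 against 12.23.

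Most transcripts of proteins that hepatocytes secrete were near background in every group. Of 41 proteins that hepatocytes secrete, 5 were detected on all 9 arrays and 28 on none, and the brightest was F12 at an intensity of 634 ± 31.5 in the control (SD, n = 3). AFP was at 105 ± 2.74 and APOA1 at 101 ± 4.67, both detected on 0 arrays. ALB was at 137 ± 13 and detected on 1 array, although this mean lies over the control arrays' detection thresholds of 117.1 to 122. Of 22 liver transcription factors 7 were detected on all 9 arrays and 9 on none, and CEBPB was the brightest, at 4100 ± 399 in the control. Of all human genes and transcripts 30.1% were detected on all 9 arrays, so these factors as a list were not detected less often. A list of 41 basal and squamous epithelial markers, written after some of their levels had been seen, had 28 detected on all 9 arrays, with KRT6A at 2140 ± 176, KRT17 at 1680 ± 129, KRT5 at 1160 ± 69.3 and TP63 at 930 ± 64.4 in the control. In AMPK shRNA 1, 8 of the 35 of these tested were higher and 27 not called, with a median log2 fold change of 0.50, and in AMPK shRNA 2, 3 were higher and 32 not called, with a median of 0.47. By array, the median over the mean of the controls was 0.16 in AMPK shRNA 2 replicate 1, against 0.63 and 0.52 in replicates 2 and 3 of that line. TGM1 rose by 1.06 and 0.95, LY6D by 1.02 and 0.79 and SCEL by 0.76 and 0.83. SCEL was near background in the control, at an intensity of 110 ± 5.84, and detected on 7 of the 9 arrays, so the size of its change is uncertain. Of 15 fibroblast, 15 endothelial and 18 immune cell markers, 2 of each list were detected on all 9 arrays.

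**Figure D5:**
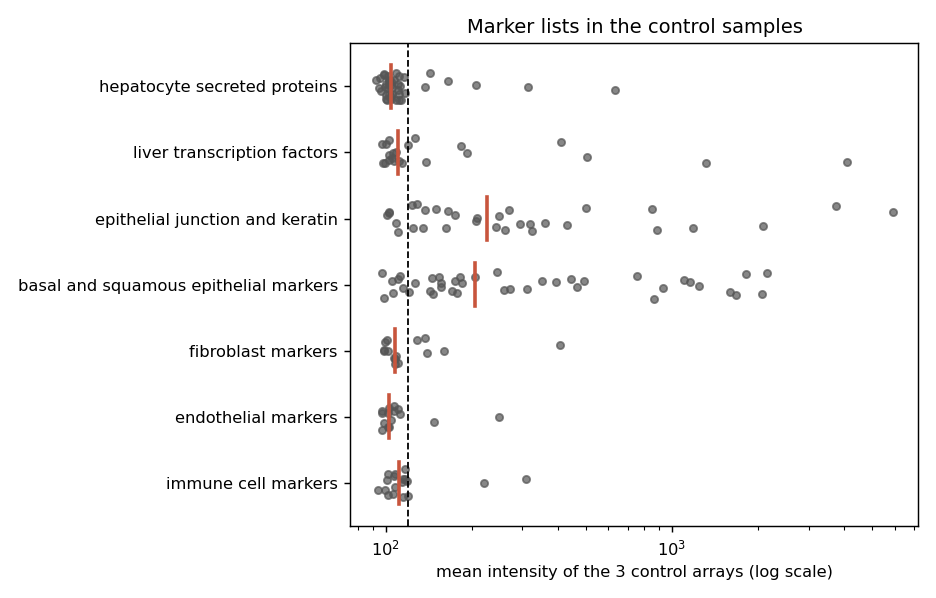
Mean intensity of each gene of 7 marker lists over the 3 control arrays (points, log axis), with the list's median (red bar) and the mean detection threshold of these arrays (dashed line). Most hepatocyte secreted proteins lie below the threshold, while KRT6A, a basal and squamous marker, reached 2140.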

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

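The signal filter was chosen after the data had been seen and the other alternatives before; it keeps genes whose intensity reaches the detection threshold on at least 3 arrays and left every count within 1.5 times. PRKAA1 kept its call in both lines in all 21 settings, with log2 fold changes of -1.55 to -0.87 and -1.68 to -0.96. No gene called in any comparison changed sign in any setting, and AMPK shRNA 2 against AMPK shRNA 1 gave 0 genes by limma in all of them. Of 91 results of named genes not called, 18 were called in some setting. Of 145 calls of named genes 47 were kept in all of these settings that tested the gene and 98 lost in at least 1, and 0 reversed; the test against a fold of 1.2, not among the 21, kept 39 of the 47, including PRKAA1. Cyclic loess and no filter kept every count within 1.5 times. For the changes below, the cause was not tested, except where the setting itself leaves out samples or tests fewer genes.

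Counts are given as higher and lower for AMPK shRNA 1, AMPK shRNA 2, both lines together, and genes called in each of the lines, where they moved by over 1.5 times. Normexp on the intensities alone with an offset of 50 gave 432 and 376, 224 and 215, 573 and 520, and 190 and 171, with 22 genes (AMPK shRNA 1) and 17 (both lines together) changed at least 2-fold. No background correction gave 511 and 442, 312 and 304, 640 and 612, and 250 and 249, with 13, 6 and 11 changed at least 2-fold. Median scaling gave 125 and 470 in AMPK shRNA 1, and 49, 151 and 46 higher in the other comparisons. The authors' value table gave 1567 lower in AMPK shRNA 1, 668 lower in AMPK shRNA 2, 231 and 1882 in both lines together and 604 lower in each of the lines, with 14, 4 and 9 changed at least 2-fold. The stricter filter, which tested 9168 genes, gave 373 and 355, 215 and 218, and 176 and 181 in each of the lines. Fits of only the groups compared gave 372 higher in AMPK shRNA 1, 18 and 10 in AMPK shRNA 2 with 7 changed at least 2-fold, and 18 and 10 in each of the lines. Trend and robust estimation gave 466 and 393, 272 and 242, 611 and 544, and 228 and 190, with 26 changed at least 2-fold in AMPK shRNA 2. Array weights gave 569 and 525, 454 and 394, 828 and 790, and 323 and 270, with 46 changed at least 2-fold in AMPK shRNA 2. The test against a fold of 1.2 gave 11 and 9, 6 and 4, 21 and 9, and 5 and 4, with 13, 5 and 13 changed at least 2-fold.

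With the replicate number as a replicate block, 150 and 100 genes were called in AMPK shRNA 1, 30 and 11 in AMPK shRNA 2 with 8 changed at least 2-fold, 193 lower in both lines together, and 30 and 11 in each of the lines. Samples of the same number showed no clear tendency to deviate together: the 9 pairs correlated at -0.05 to 0.19 and other pairs at -0.26 to 0.19. Of 9 samples, 4 correlated best with one of their own number. Between the AMPK shRNA lines, the pairs of the same number correlated at 0.19, -0.05 and 0.14. With so few pairs, a batch shared by samples of the same number is not excluded. The replicate block changed the call of 3 of 144 list results.

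Without one array at a time, AMPK shRNA 1 had 19 to 488 genes higher, 9 to 403 lower and 14 to 62 changed at least 2-fold; AMPK shRNA 2 had 7 to 367, 5 to 234 and 5 to 62; both lines together 59 to 747, 32 to 624 and 14 to 62; and 7 to 273 higher and 5 to 152 lower were called in each of the lines. The lowest counts came without a control array and the highest without AMPK shRNA 2 replicate 1, and fewer samples alone lower the counts. Without AMPK shRNA 2 replicate 1, 4 list results also reversed by camera, from not called to called in the other direction. In AMPK shRNA 2 against AMPK shRNA 1, the median of cholesterol synthesis went to -0.11 (from 0.05 with all arrays, and up to 0.14 without another array). That of the interferon list went to 0.13 (from -0.01, down to -0.10) and that of MYC targets to -0.08 (from 0.07, up to 0.14). In AMPK shRNA 2 against control, that of the hypoxia list went to 0.19 (from -0.01, down to -0.14). Over 22 settings, this one included, these medians changed sign in 2, 4, 2 and 4, so their sign does not rest on that sample alone. Of 144 list results, the estimated correlation ended 36 calls, median scaling 8, the stricter filter 14 and the authors' values 6, while other settings ended at most 1, apart from arrays left out (0 to 9). Calls were gained too: 15 with no filter, 13 with the authors' values, 13 without AMPK shRNA 2 replicate 1, 9 with no background correction, 5 with the stricter filter, and at most 7 in any other setting. In AMPK shRNA 2 against AMPK shRNA 1, where 0 of 36 lists were called, 14 were called in at least 1 setting, so that 0 depends on the processing.

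Not run were each probe by itself and the mean over probes, because the table holds 1 value per gene, and the slide as a block, because neither table nor labels give a slide. Signal over background limits dim genes: the negative controls had an SD of 7.07 to 8.53 around 98.3 to 107. Entries whose detection p is a whole multiple of the step counted as detected from 111.8 to 122, and below that a change is hard to see. For the other entries this limit does not hold: PRKAG2, at 170 ± 6.05 in the control, was detected on 2 of those 3 arrays.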

Other observations

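Tests of the low liver transcripts, the array quality and culture state of AMPK shRNA 2 replicate 1, its bearing on the shared genes, and the annotation terms were chosen after the results were seen. The others were fixed before.

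Transcripts of most hepatocyte secreted proteins lay near background in all 9 samples labelled Hep3B, and the values argue against 3 explanations. The arrays registered other abundant messages, since 96.2% of 106 ribosomal protein and oxidative phosphorylation genes were detected on all 9 arrays. The AMPK shRNAs did not lower them, since 12.2% of 41 hepatocyte secreted proteins were detected on all 3 control arrays, and a sizeable share of liver cells would have brought these proteins up, but 12.2% reached the detection threshold on all 9. Cultured cells other than the labelled line stay open: 68.3% of 41 basal and squamous markers were detected on all 9 arrays, against 30.1% of all genes, but that list was written after some of its levels had been seen and cannot test the explanation. A subline that lost liver expression, with 5 secreted proteins left, cannot be told apart from this without genotype data.

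AMPK shRNA 2 replicate 1 stood apart from its line. A poor array is argued against by 4 of 4 array measures (beads, genes detected, mean and SD of the negative controls) within the range of the other 8 arrays. None of these measures RNA integrity, so a poorer RNA sample is not excluded. A mislabelled control is argued against by PRKAA1 at 6.14, against 7.77 to 7.95 in the controls. Another state of the culture stays open: the hypoxia list lay at -0.48 against the others of the line, but this value had been seen before the test was chosen, and the interferon list (-0.43), cholesterol synthesis (0.47) and MYC targets (0.46) lay about as far off. The hypoxia list was also unequal within AMPK shRNA 1 (-0.30, -0.22 and 0.10 over the controls), so its spread is not confined to this sample. The labels record neither density nor oxygen, and no biological explanation was tested.

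The genes called in both lines may reflect an effect of the AMPK shRNAs, a difference of the only control line, or both. A covariance of 0.045 against a highest simulated 0.0119 argues against chance values of the shared controls alone only as these were simulated. The simulated values lay close together (mean 0.0112), while in AMPK shRNA 2 replicate 1 whole lists lay off together, by -0.48 to 0.47. A deviation shared by many genes in the controls is therefore not excluded. Whether the culture state behind the deviating sample also set the shared genes stays open: of the 430 genes called in both lines without that sample, with the normalized values left as they were (normalizing the other 8 arrays anew gave 273 higher and 152 lower), 79.3% lay beyond all 3 controls in it. Of the 421 genes called in AMPK shRNA 1, 96% did so, with a slope of 0.64 on the change in that line (0.89 and 0.87 in the other samples of AMPK shRNA 2), but this is 1 array, and the genes were chosen against the same controls, so the 25% of unchosen genes is not their chance level. The design has 1 control line, so an effect of the shRNAs cannot be told apart from a peculiarity of that line.

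Other splits of the arrays were counted for each comparison. Of 84 splits into 3 and 6 arrays, 1, the real one, gave as many genes as the 808 of control against both lines (highest other 7). Of 100 splits into 3 groups of 3, the real one and others drawn at random, 2 gave at least as many genes called in both groups as the real 148. The other one gave 167 and kept the 3 controls together as the control group. The 98 that did not keep them together as the control group gave at most 0. Both counts thus set the controls against the rest and do not bear on how the other 6 arrays were labelled. Splits that mix controls with the lines also widen the spread within groups, which lowers their counts. The splits took the arrays as independent, which the labels do not state. Chance between cultures or lines is therefore not excluded. With 3 against 3 arrays the 10 splits are too few for a share under 0.05: AMPK shRNA 1 gave 651 genes in 1 split (highest other 0), AMPK shRNA 2 gave 28 in 1 split (highest other 0), and AMPK shRNA 2 against AMPK shRNA 1 gave 0, reached by 10 of 10 splits (highest other 1).

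The 47 higher and 42 lower shared genes with an annotation were tested for 399 biological process terms of 10 to 300 genes against the 7753 annotated genes tested. No term passed, with a smallest Benjamini-Hochberg adjusted p of 0.614 by Fisher's exact test. Of the 92 ERCC controls, at most 2 were detected on an array, no more than chance gives at a detection p under 0.05.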
